A study of Homo sapiens with 4 samples.

How the data were processed

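The study measured chromatin occupancy in primary human erythroid cells, with 1 library for each of BPTF, SET1, USF1 and USF2. Per the labels' protocols, CD34-selected cells were cultured with erythropoietin at 3 U/ml and other factors for 9 to 14 days, and the stage was checked by flow cytometry for CD71 and CD235a. Chromatin was fixed with 1% formaldehyde for 10 min, sheared by sonication to about 200 to 400 bp and precipitated with 20 μg of antibody. A control immunoglobulin is mentioned in those protocols, and no control library was used here. The protocols give the same antibody for USF1 and USF2, while the sample's antibody field gives another one for USF2, so which was used for USF2 is open. An antibody against a modified histone H4 is also mentioned and was not analysed here.

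The deposited files are peak lists, 1 per library, with chromosome, start, end, peak name and score. Per the submitters' processing notes the build was hg18 and CASAVA 1.7.0 was used. The peak names in the files are those that MACS writes. The MACS version, the aligner, the treatment of duplicate reads and whether a control was used in peak calling are not given in the sources used here. The deposited score runs from 50 upwards, with several peaks tied at 3100. In older MACS output this column is minus 10 times the decimal logarithm of the peak p-value, but nothing in the files says so, and it was used only to rank peaks within 1 list. The scores and widths are the authors' own values. The build was checked against chromosome lengths: no peak ended beyond its chromosome in hg18, while 58 to 364 peaks per list did so in hg19 and 250 to 1040 in hg38. A start below 0 (3 BPTF and 4 SET1 peaks) was set to the start of the chromosome. Coordinates in the text are 1-based.

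Peaks on the autosomes and X were used. The Y chromosome was left out, as were 2 USF2 peaks on the mitochondrial sequence. Chromosome lengths of hg18 came from GenomeInfoDb 1.38.1. The 266 assembly gaps of hg18 were derived from the contig placement file of IRanges 2.36.0. No hg18 annotation or sequence was used here, so peaks were not assigned to genes, promoters or sequence motifs. The planned promoter, gene list and E-box comparisons were therefore not run.

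An overlap was counted when peaks shared at least 1 bp. The number of overlapping peaks of one list was compared with 1000 circular shifts of the other list along each chromosome, which keep peak widths and spacing (one-sided permutation p, Benjamini-Hochberg adjustment over 6 pairs). Regions with all 4 proteins were counted after merging of touching peaks, with all lists shifted. Co-occurrence tables were tested with Fisher's exact test and given with Wald intervals of the log odds ratio. USF1 and USF2 were compared at BPTF and SET1 peaks with the exact McNemar test after matching of list length by score. Peak score by company was compared as the share of pairs in which the accompanied peak scored higher, with a permutation test of 100000 resamples (10000 for alternatives). Groups of peaks were counted with a limit of 10 kb between neighbours and compared with 100 random placements. These p-values treat peaks as units and describe the 4 lists. They do not measure the spread between experiments, which 1 library per protein cannot give.

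The named positions followed a rule fixed before the data were examined. It took the 5 highest-scored peaks of each list and the 10 four-protein regions with the best mean within-list rank. It also took the 5 densest groups of peaks of each list. How density is measured was not part of the rule, and the groups with the most peaks were taken. The tie at 3100 among USF2 peaks was broken by chromosome order. Alternatives fixed at the same time were an overlap of at least 50% of the shorter peak, centres within 250 bp, the higher-scored 50% of each list, local shifts of 20 to 100 kb, lists of equal length, and stratification by width. Local shifts moved each peak by its own distance and direction, so they did not keep the spacing of neighbouring peaks. The shares by score class, the densities per chromosome, the distances to assembly gaps and the test of BPTF against SET1 at joint USF regions were not among the planned results. Shifts within assembled sequence, removal of peaks within 1 Mb of a gap or chromosome end, stratification by USF score and the comparison of USF1 with USF2 by centres were added after the data had been seen. The overlap test was tested on simulated data with the BPTF list, 100 shifts and 20 random lists with the sizes and chromosomes of the SET1 list. With no planted sharing the mean excess was 0.97-fold and 0 of 20 simulations passed 0.05. With copies of 20% of the BPTF peaks added to the random lists, 20.0% were recovered and 20 of 20 passed. The random peaks were placed evenly along each chromosome, without the clustering of the real lists. False positives from clustering or from a regional density common to 2 lists were therefore not tested. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.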

Results

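Chromatin binding of 4 proteins was mapped by chromatin immunoprecipitation and sequencing in primary human erythroid cells grown from CD34-positive stem and progenitor cells. The cells had been expanded for 3 days without erythropoietin, the hormone that drives red cell production, and then differentiated with it into nucleated erythroid cells of the R3/R4 stage. BPTF is the large subunit of the chromatin remodelling complex NURF, SET1 is a histone H3 lysine 4 methyltransferase, and USF1 and USF2 are related helix-loop-helix proteins that bind the E-box CACGTG as homodimers or heterodimers. The question that the design implies is whether NURF and SET1 occupy the same places in erythroid chromatin as each other and as the USF proteins. Each protein was assayed in 1 library, so the results describe 4 peak lists and hold no replicate error. Intervals on shares are 95% Wilson intervals and cover counting error only. Read depth is unknown, because the lists carry no read counts.

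On the autosomes and X the lists held 13003 BPTF peaks, 11989 SET1 peaks, 56648 USF1 peaks and 52354 USF2 peaks. BPTF and SET1 peaks were wide, with medians of 897 bp and 876 bp. USF1 and USF2 peaks were narrower, with medians of 297 bp and 269 bp. The BPTF peaks covered 14.0 Mb, the SET1 peaks 12.3 Mb, the USF1 peaks 23.4 Mb and the USF2 peaks 19.4 Mb of the hg18 genome. The narrowest peak was 332 bp in the BPTF list and 370 bp in the SET1 list, against 104 bp in the USF1 list and 94 bp in the USF2 list. The lists therefore fell into a wide pair and a narrow pair. The pairs also share a kind of target (chromatin complex or sequence-specific factor), so any difference in library handling between them could not be separated from the target.

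BPTF and SET1 peaks coincided far more often than shifted lists did. Of the 13003 BPTF peaks, 5122 overlapped a SET1 peak (39.4%, interval 38.6 to 40.2), and 5091 of the 11989 SET1 peaks overlapped a BPTF peak (42.5%, interval 41.6 to 43.4). The centres of overlapping peaks lay a median of 98 bp apart. Most of these shared places carried neither USF protein: 3520 BPTF peaks, 27.1% of the list, met SET1 alone. Sharing followed the peak score. In the lowest-scored 10% of BPTF peaks 13.8% met a SET1 peak, and in the highest-scored 10% it was 1235 of 1300 peaks (interval 93.7% to 96.1%). In the SET1 list the corresponding shares that met a BPTF peak were 12.4% and 98.2%. Across the 5122 shared BPTF peaks the scores of both lists were correlated (Spearman's rho 0.66, across peaks, which are not independent replicates). After 1000 circular shifts of the SET1 list along each chromosome a mean of 135 BPTF peaks (SD 19.8) overlapped by position alone, a 37.9-fold excess of the observed number (circular-shift permutation, one-sided, p = 0.001 raw and after Benjamini-Hochberg adjustment over 6 pairs, the smallest that 1000 shifts can give). Shifts of only 20 to 100 kb, which keep each peak in its neighbourhood, left a 10.4-fold excess, and with centres within 250 bp of each other it was 127-fold.

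**Figure D1:**
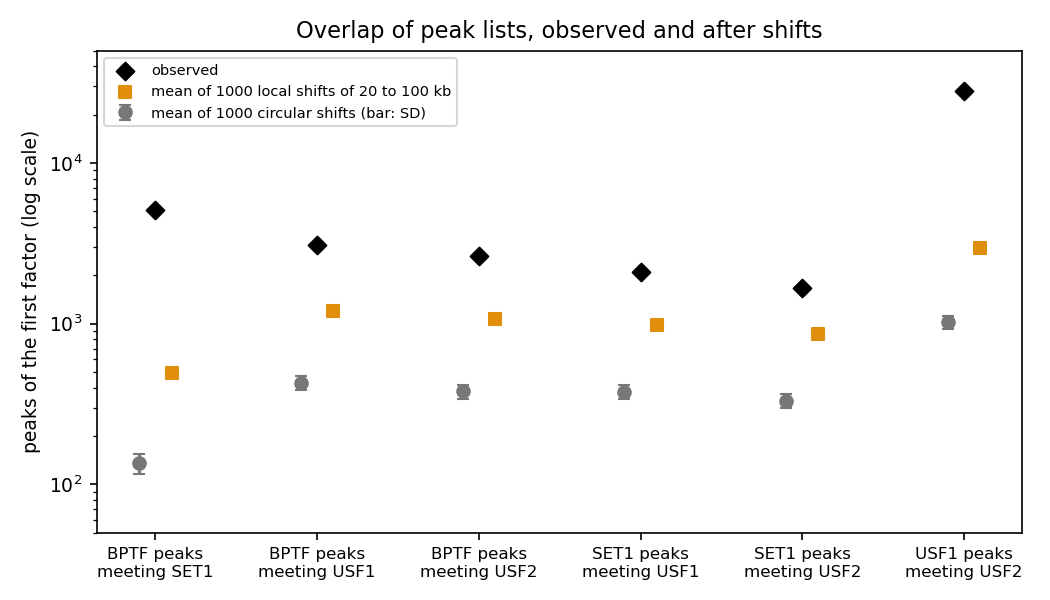
Number of peaks of the first-named factor that overlap a peak of the second (y axis, log scale) for the 6 pairs of lists (x axis). Black diamonds are the observed numbers, grey circles the mean of 1000 circular shifts with bars of 1 SD, and orange squares the mean of 1000 local shifts. The observed numbers, from 1667 to 28137, lie above both kinds of shift in all 6 pairs.

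USF1 and USF2 peaks also coincided far more often than shifted lists did. Of the USF1 peaks, 28137 met a USF2 peak (49.7%, interval 49.3 to 50.1), and 29563 USF2 peaks met a USF1 peak (56.5%, interval 56.0 to 56.9). Their centres lay a median of 65 bp apart. The remaining 28511 USF1 peaks and 22791 USF2 peaks had no partner in the other USF list. Nearly all high-scored peaks were shared: 99.0% of the highest-scored 10% of USF1 peaks and 99.5% of the highest-scored 10% of USF2 peaks, against 30.1% and 33.7% in the lowest-scored 10%. Circular shifts of the USF2 list gave a mean of 1020 overlapped USF1 peaks, a 27.6-fold excess (circular-shift permutation, one-sided, p = 0.001). The excess was 9.55-fold over local shifts and 46.4-fold among the higher-scored 50% of both lists. The labels differ on the USF2 antibody, and in one reading it was the one used for USF1, so that this overlap and every other comparison of USF1 with USF2 here would be between 2 libraries of the same antibody.

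USF peaks were found at a minority of BPTF and SET1 peaks. USF1 lay at 3090 BPTF peaks (23.8%) and USF2 at 2621 (20.2%, interval 19.5 to 20.9). At SET1 peaks USF1 was found at 2096 (17.5%, interval 16.8 to 18.2) and USF2 at 1667 (13.9%, interval 13.3 to 14.5). At least 1 USF protein was present at 3756 BPTF peaks (28.9%) and at 2636 SET1 peaks. In the other direction, 8.76% of USF1 peaks and 8.17% of USF2 peaks met BPTF or SET1. The overlap with circularly shifted USF lists was exceeded 7.19-fold for BPTF with USF1, 6.92-fold for BPTF with USF2, 5.56-fold for SET1 with USF1 and 5.03-fold for SET1 with USF2 (circular-shift permutation, one-sided, p = 0.001 for each pair). Over local shifts these excesses were 2.58-fold, 2.44-fold, 2.14-fold and 1.92-fold, each again at p = 0.001 in the same permutation test. With centres within 250 bp they were 12.9-fold, 12.0-fold, 9.33-fold and 8.11-fold.

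**Figure D2:**
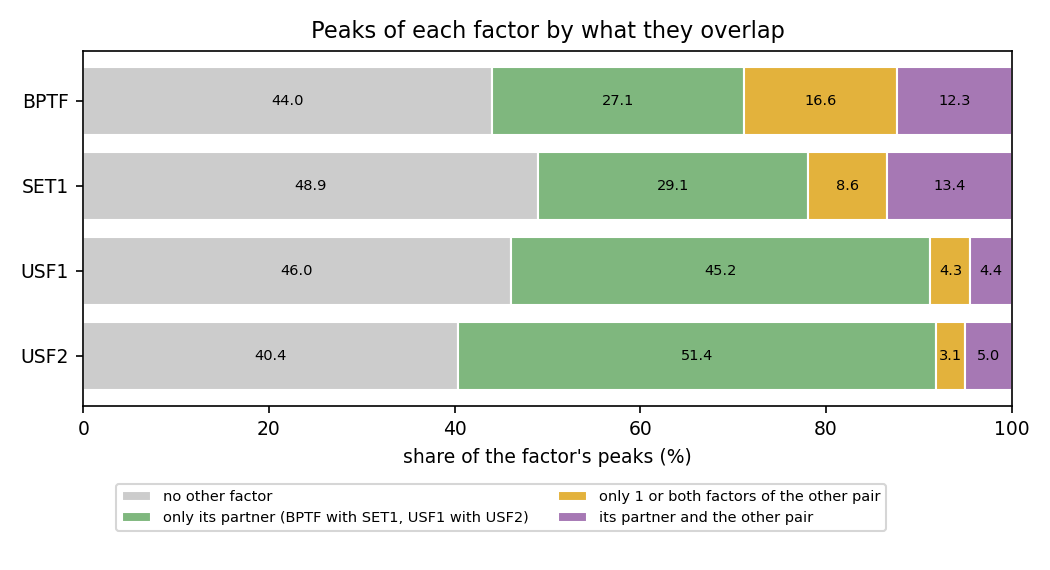
Share of each factor's peaks (x axis, percent) that overlap no other factor, only the partner in the same pair (BPTF with SET1, USF1 with USF2), only the other pair, or both, with the percentages printed on the bars. The peaks with no other factor make up 44.0% of BPTF, 48.9% of SET1, 46.0% of USF1 and 40.4% of USF2 peaks.

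The scores of BPTF and USF peaks at the same place were only loosely related. Spearman's rho across shared peaks was 0.12 for BPTF with USF1 and 0.11 for BPTF with USF2. For SET1 it was 0.07 with USF1 and 0.06 with USF2, against 0.61 for USF1 with USF2. The share of BPTF peaks with USF1 went from 12.6% in the lowest-scored 10% to 32.9% in the highest-scored 10%, and levelled off over the top classes. The share of SET1 peaks with USF1 went from 9.92% to 24.2%.

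**Figure D3:**
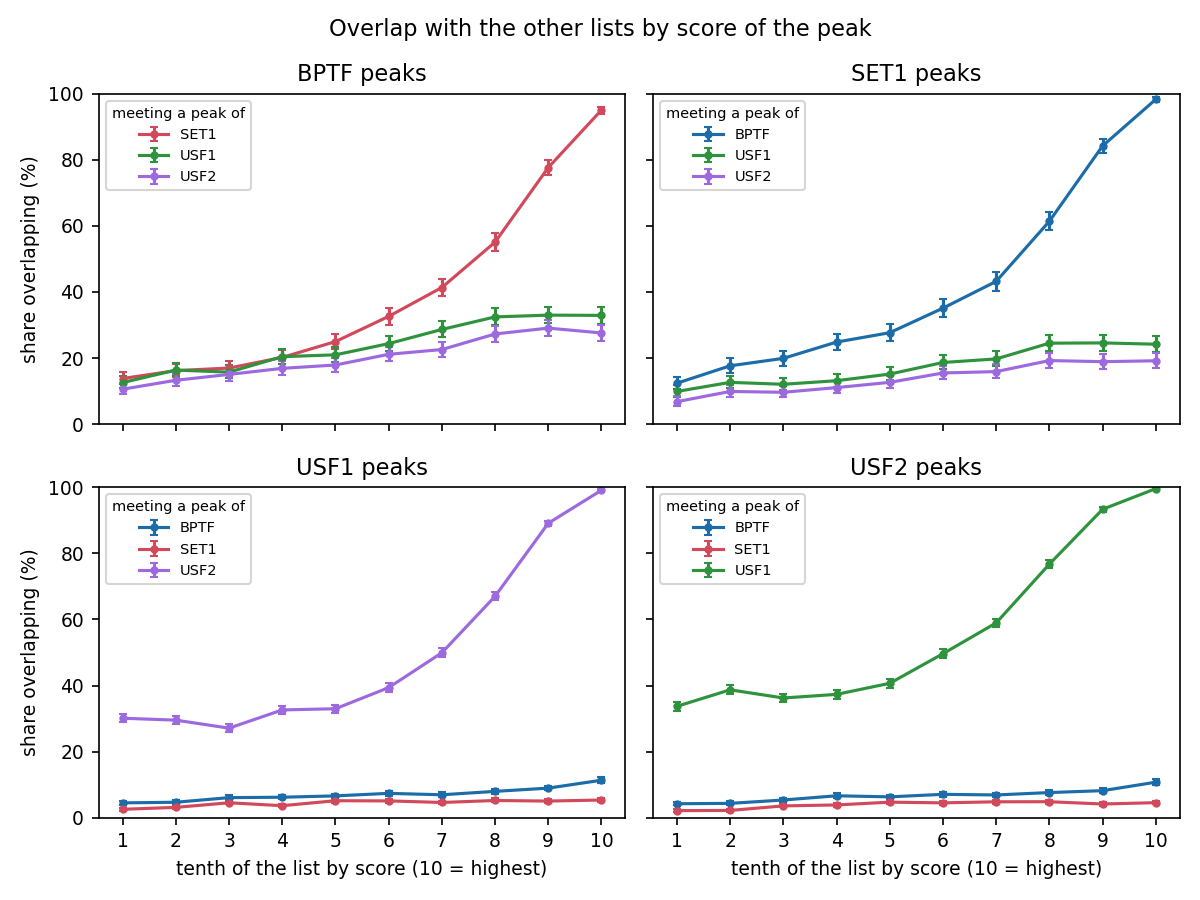
Share of each factor's peaks that overlap a peak of each other factor (y axis, percent, with 95% Wilson intervals) by class of score within the list (x axis, 10 equal classes, 10 the highest). The curves between BPTF and SET1 and between USF1 and USF2 reach 98.2% to 99.5% in the top class for SET1, USF1 and USF2 peaks and 1235 of 1300 peaks for BPTF, and the curves across the pairs stay at or below 33.0%.

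USF1 was found more often than USF2 at peaks of both chromatin proteins. With the USF1 list reduced to the 52354 highest-scored peaks, the length of the USF2 list, 1106 BPTF peaks had USF1 without USF2 and 705 had USF2 without USF1, while 1916 had both. The ratio was 1.57 (exact McNemar test, two-sided, p = 3.8e-21). At SET1 peaks the numbers were 943, 562 and 1105, a ratio of 1.68 (exact McNemar test, two-sided, p = 7.0e-23). USF1 peaks were somewhat wider than USF2 peaks. By centres within 250 bp, a criterion added after the data had been seen, the ratios were 1.40 and 1.56.

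The coincidence of BPTF and SET1 was also seen at USF peaks. Among USF1 peaks, 39.4% of those with BPTF also had SET1, against 1.79% of those without BPTF. The share of all BPTF peaks that met SET1 was 39.4% as well, so the table largely restates the overlap of both lists. The odds ratio was 35.7 (95% interval 32.6 to 39.1), from 1584 USF1 peaks with both, 2434 with BPTF alone, 942 with SET1 alone and 51688 with neither. Among USF2 peaks 37.8% of those with BPTF and 1.51% of those without had SET1, an odds ratio of 39.8 (95% interval 36.0 to 43.9). Among the higher-scored 50% of all lists the odds ratios were 56.9 and 60.9. Neighbouring peaks can lie in 1 wide BPTF or SET1 peak and are not independent, so the intervals are narrower than the true uncertainty.

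Regions bound by both USF proteins were compared with regions bound by 1 of them. After merging of touching peaks, 26666 regions held both and 51282 held 1. BPTF was present at 7.73% (interval 7.41 to 8.05) of the joint regions and 5.94% (interval 5.74 to 6.15) of the single ones, an odds ratio of 1.33 (Fisher's exact test, two-sided, p = 3.1e-21). SET1 was present at 4.27% and 4.31%, an odds ratio of 0.99 (95% interval 0.92 to 1.07; Fisher's exact test, p = 0.81). Joint regions were wider, with a median of 547 bp against 239 bp, and within 5 classes of region width the odds ratio was 1.35 for BPTF and 1.29 for SET1. Within 5 classes of USF score, a stratification added after the data had been seen, it was 0.88 for BPTF and 0.70 for SET1. All 4 stratified values passed the threshold of 0.05 in the Mantel-Haenszel test.

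All 4 proteins had a peak in 862 merged regions, 0.944% of the 91268 regions of the 4 lists, with a median width of 1625 bp. Circular shifts of every list gave a mean of 0.93 such regions and at most 5 (circular-shift permutation, one-sided, p = 0.001). Local shifts gave a mean of 45.5, so the observed number was 18.9 times higher. Both kinds of shift moved each list separately and so also broke up the overlaps of BPTF with SET1 and of USF1 with USF2. The excess therefore includes those overlaps and does not test sharing among all 4 proteins beyond them. A further 1131 regions held BPTF with both USF proteins but no SET1, 309 held SET1 with both USF proteins but no BPTF, and 3352 held BPTF and SET1 alone. All 4 peak centres lay within 500 bp in 573 regions, and 367 regions held all 4 proteins when only the higher-scored 50% of each list was used.

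The 10 four-protein regions with the best mean rank were led by chromosome 2, positions 114076709 to 114078756 (hg18), with scores of 1414 for BPTF, 909 for SET1, 2917 for USF1 and 2896 for USF2. A region of chromosome 7, 5528260 to 5540120, contained the widest BPTF peak of the list, 11466 bp with a score of 3100, and scores of 1263 for SET1, 453 for USF1 and 1005 for USF2. A second region of chromosome 7, 44024789 to 44025934, had scores of 715, 338, 1524 and 1298 in the same order. The others were on chromosome 15 (100318969 to 100319489), chromosome 20 (26136498 to 26138666), chromosome 10 (135372028 to 135373881), chromosome 16 (29531526 to 29532992), chromosome 9 (78375924 to 78377259) and chromosome 1 (16898319 to 16904275 and 143920112 to 143921693). Of these 10 regions, 3 lay within 100 kb and 5 within 1 Mb of an assembly gap or chromosome end. No gene is named for any region, because no hg18 gene annotation was used here.

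Peaks that met another protein scored higher than peaks that stood alone, in all 4 lists. The median score was 92.7 against 60.6 for BPTF, 95.3 against 59.7 for SET1, 144 against 82.3 for USF1 and 167 against 91.6 for USF2. Among peaks that met a single other protein, the difference was largest with the partner of the same pair. BPTF peaks that met only SET1 had a median of 107, against 67.4 with only USF1 and 66.1 with only USF2. USF1 peaks that met only USF2 had a median of 150, against 90.1 with only BPTF and 93.6 with only SET1. The SET1 and USF2 lists went the same way, with 110 for SET1 peaks that met only BPTF and 171 for USF2 peaks that met only USF1. Peaks that met all the other proteins had medians of 129 for BPTF, 194 for USF1 and 198 for USF2, higher than with the partner alone. For SET1 it was 104, lower than with the partner alone. The probability that a peak with company outscored a peak without was 0.772 for BPTF, 0.778 for SET1, 0.752 for USF1 and 0.751 for USF2 (permutation test over peaks, 100000 resamples, two-sided, p = 1e-05 for each list, the smallest that they can give). Peaks with company were also wider, with medians of 1098 bp against 737 bp for BPTF, and within 5 classes of peak width the probability was 0.677 to 0.690 over the 4 lists.

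The BPTF and SET1 lists had several of their highest peaks in common, and the USF lists had their highest peaks elsewhere. Both the BPTF and the SET1 list had among their 5 highest peaks one on chromosome 1 (BPTF 141476824 to 141484259) and one on chromosome 16 (BPTF 44943135 to 44945396) that reach an assembly gap. A second SET1 peak on chromosome 16, 44947287 to 44954701, lay 3.98 kb from that gap. Both lists also had a peak on chromosome 16 that starts at 88625240 in the BPTF list and lies 195 kb from a gap or chromosome end. The remaining BPTF peaks of the 5 were on chromosome 5 (137826691 to 137835217), with both USF proteins but no SET1, and on chromosome 7 (5528260 to 5539725), with all 3 other proteins, 977 kb and 5051 kb from a gap or end. The remaining SET1 peak was on chromosome 17, 70021186 to 70023341, again with all 3 others. The 5 highest USF1 peaks, with scores from 3147 to 3217, all met USF2 and none met BPTF or SET1. They lay on chromosome 9 (123895286 to 123895692), chromosome 2 (3630608 to 3631356 and 219750765 to 219751759) and chromosome 3 (51403446 to 51403988 and 20202307 to 20203113). The peak at 3630608 was 73.4 kb from a gap or end. The last of those on chromosome 3 was also the highest USF2 peak, with a score of 3122. Below it 14 USF2 peaks tied at 3100. The first 4 of them in chromosome order lay on chromosome 1, at 16843151 and 152797690, and on chromosome 7, at 882296 and 4781345, and those at 16843151 and 882296 also met BPTF. The USF2 peak at 16843151 was 153 kb from a gap or end.

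Peaks were clustered in all lists. Groups of at least 5 peaks with no more than 10 kb between neighbours numbered 130 for BPTF, 88 for SET1, 2225 for USF1 and 1991 for USF2. Peaks placed at random on the same chromosomes gave means of 0.30, 0.12, 299 and 241 groups (permutation of positions, 100 placements, one-sided, p = 0.01 for each list, the smallest possible). The groups held 6.75% of BPTF, 5.15% of SET1, 34.8% of USF1 and 33.1% of USF2 peaks. The largest groups of BPTF and of SET1 had 3 places in common: chromosome 16 from 44943135, with 29 BPTF and 24 SET1 peaks, chromosome 21 near 9.80 Mb, with 20 and 23, and chromosome 2 near 91.1 Mb, with 18 and 19. They lay 0 to 164 kb from an assembly gap. The other BPTF groups were on chromosome 10 at 39120399 to 39193870, with 18 peaks, as many as on chromosome 2, and chromosome 20 at 29269764 to 29297075, with 12. They lay 1.07 kb and 2.19 kb from a gap. The other SET1 groups were on chromosome 16 at 33772067 to 33810021, with 13 peaks, and chromosome 1 at 226530171 to 226576234, with 12. Their distances to a gap or end were 121 kb and 4666 kb. The largest USF1 group, 84 peaks over 261 kb, was on chromosome 19 at 1013308 to 1274450. Further USF1 groups lay on chromosome 19 at 1738209 (66 peaks), chromosome 16 at 87019942 (59), chromosome 11 at 752324 (59) and chromosome 20 at 60358649 (57). Those on chromosomes 16 and 20 were 53.1 kb and 3.02 kb from a gap or end, and the other USF1 groups 237 to 1727 kb. The largest USF2 group, 121 peaks over 379 kb, was on chromosome 9 at 138952239 to 139330887. It was followed by groups on chromosome 16 at 87031310 (76 peaks), chromosome 7 at 150265743 (58), chromosome 19 at 843968 (56) and chromosome 11 at 752511 (52). The USF2 group on chromosome 16 was 64.4 kb from a gap or end, and the other USF2 groups 282 to 3478 kb.

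Densities per Mb were taken over the full chromosome length, assembly gaps included, although gaps can hold no mapped reads. By this measure, among the autosomes, all 4 lists were densest on chromosome 19, a gene-rich chromosome, and sparsest on chromosome 13. Chromosomes with long gaps are understated in this way. Whether chromosome 13 is also the sparsest over assembled sequence was not tested. On chromosome 19 the density was 69.8 USF1 and 67.5 USF2 peaks per Mb, 3.59 and 3.76 times the autosomal mean of each list. BPTF reached 11.8 and SET1 10.1 peaks per Mb there, 2.62 and 2.43 times their means. Chromosome 19 held 7.99% (interval 7.76 to 8.21) of autosomal USF1 peaks against 5.83% (interval 5.44 to 6.24) of BPTF peaks. On chromosome 10 the order was the other way round, with 4.20% (interval 4.04 to 4.37) of USF1 against 5.56% (interval 5.18 to 5.97) of BPTF and 5.84% (interval 5.43 to 6.27) of SET1 peaks. The density on chromosome 13 was 0.51 and 0.52 times the mean for BPTF and SET1, and 0.37 times for both USF proteins.

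**Figure D4:**
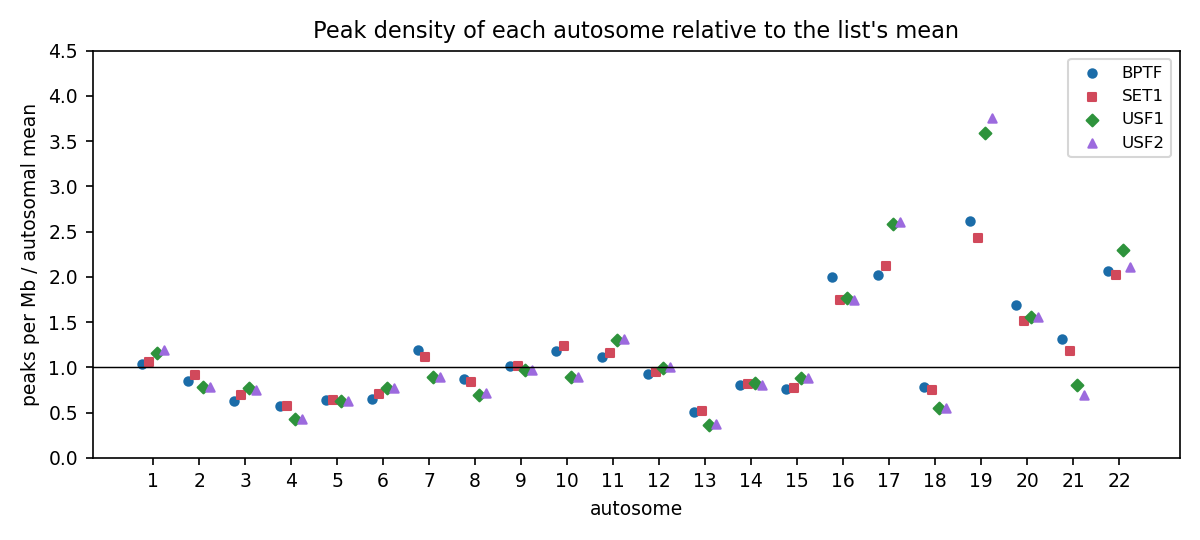
Peaks per Mb of full chromosome length, assembly gaps included, on each autosome (x axis) divided by the autosomal mean of the same list (y axis, linear ratio), 1 point per list. The line at 1 is the mean, and on chromosome 19 the USF points stand at 3.59 and 3.76, above BPTF at 2.62 and SET1 at 2.43.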

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

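The test of the difference described here was chosen after the lists had been seen. BPTF and SET1 differed in how they were divided between joint and single USF regions. Among USF regions with exactly 1 of the chromatin proteins, BPTF and SET1 numbered 1232 and 310 in joint regions and 1872 and 1036 in single regions. The odds ratio was 2.20 (95% interval 1.90 to 2.54; Fisher's exact test, two-sided, p = 8.9e-28).

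Joint regions are wider and hold higher USF peaks, and either property could give such a difference without a preference of BPTF for joint binding. Within 5 classes of region width the odds ratio was 1.24 (95% interval 1.02 to 1.49), within 5 classes of USF score rank 1.82 (1.51 to 2.18), and within both together 1.27 (1.02 to 1.57). All 3 intervals stay above 1. For USF score alone this argues against it as the whole cause, but most of the excess went with width. The lower bounds of 1.02 leave little margin, because neighbouring regions are not independent and the true intervals are wider. Width as the whole cause therefore stays open. A difference between the proteins and a difference between the antibodies or libraries also stay open, with no replicate to separate them.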

How the results depend on the processing

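No paired analysis was possible because each protein had 1 library. For the same reason no replicate could be left out, and no depth is known from which a detection limit could be set. The promoter, gene list and E-box comparisons and the removal of promoter peaks were planned and not run, for want of an hg18 annotation or sequence. All 42 alternatives of the 6 pairwise overlaps kept an excess above 1 at a permutation p of 0.001, with folds from 1.92 (SET1 with USF2, local shift) to 127 (BPTF with SET1, centres within 250 bp). Alternatives chosen after seeing the data gave 4.55-fold to 34.5-fold for shifts within assembled sequence, and 2.09-fold to 14.4-fold for local shifts without peaks within 1 Mb of a gap or chromosome end. The list lengths did not change by merging of touching peaks, and the mitochondrial sequence added 2 USF2 peaks (52356). The score comparisons (probability 0.677 to 0.744), the odds ratios of BPTF with SET1 among USF peaks and the USF1 to USF2 ratios kept their direction and side of the threshold in every alternative run. The number of four-protein regions was 573 with all centres within 500 bp and 367 in the higher-scored 50% of each list, as stricter criteria must reduce it, both above means of 0.037 and 0.139 after separate shifts of each list (permutation p = 0.001). Groups of peaks numbered 55 (BPTF), 44 (SET1), 1355 (USF1) and 1242 (USF2) with 5 kb between neighbours, and 39, 38, 481 and 392 in the higher-scored 50%, which again holds fewer peaks. For BPTF at joint USF regions the odds ratio of 1.33 was 1.35 within classes of region width, 1.26 in the higher-scored 50% and 1.41 with 50% overlap, and turned to 0.88 within classes of USF score, added after seeing the data. For SET1 the odds ratio of 0.99 turned to 1.29 within classes of region width, chosen before the data were examined, and was 0.70 within classes of USF score, both past the threshold. The cause was not tested.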

Other observations

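The tests of BPTF and SET1 near gaps and at USF sites, and of unshared USF peaks above the median score, were chosen after the lists had been seen. The other tests of the USF lists and that of the highest shared BPTF and SET1 peaks were written down before their results. Peaks of the chromatin proteins were concentrated beside assembly gaps and chromosome ends. Within 100 kb of a gap or end lay 6.06% (95% Wilson interval 5.66 to 6.48) of BPTF and 6.12% (5.71 to 6.57) of SET1 peaks, against means of 1.96% and 1.98% and highest values of 3.48% and 2.98% after shifts along the assembled sequence. For USF1 and USF2 the shares were 2.19% and 2.20%, against shifted means of 2.02% for both and highest values of 3.23% and 3.30%. BPTF peaks shared with SET1 were near a gap or end in 9.39% of cases (8.62 to 10.2), and those not shared in 3.90% (3.49 to 4.35). Shared BPTF peaks without a USF protein reached 10.1% (9.19 to 11.2). Of the 862 four-protein regions, 6.73% (5.24 to 8.60) lay this close.

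The relation of USF presence to SET1 at BPTF peaks depended on the stratification. SET1 was at 42.7% (41.1 to 44.2) of the 3756 BPTF peaks with a USF protein and at 38.1% (37.1 to 39.1) of the 9247 without, an odds ratio of 1.21 (Fisher's exact test, two-sided, p = 1.4e-06). The direction turned within 5 classes of BPTF peak width, with an odds ratio of 0.65 (0.60 to 0.71), and within 5 classes of BPTF score, with 0.78 (0.71 to 0.86).

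BPTF and SET1 had the largest excess over circular shifts among the 6 pairs, 37.9-fold. USF1 and USF2 shared more of their peaks, and over local shifts their excess was 9.55-fold against 10.4-fold for BPTF and SET1. Sequence that is present in more copies than the assembly holds gathers reads beside gaps, and might give the same peaks in the BPTF and SET1 libraries. Without the peaks within 1 Mb of a gap or chromosome end, 3064 of 8803 BPTF peaks still met SET1. In the full list it was 5122 of 13003. The mean after local shifts fell from 494 to 212, so the excess was 14.4-fold (10.4-fold with them). The remaining sharing argues against sequence beside gaps and ends as the whole cause. Multi-copy sequence farther from gaps was not removed, so that part stays open. Coincidence at USF sites is argued against as the whole cause as well. Of the shared BPTF peaks 31.3% (30.0 to 32.6) met a USF protein, against 28.9% of all BPTF peaks. An artefact of mapping or copy number common to all libraries stays open. Of the highest-scored 10% of shared peaks 41.8% (37.6 to 46.1) met a USF peak, more than the share among all shared peaks. It lay between the share chosen beforehand for such an artefact and the lower one chosen against it. Neither was derived from data, so the value does not decide. Whether each list was called against a control is not given. A preference of both complexes for the same chromatin also stays open, untested without replicates or a control list.

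For the 28511 USF1 peaks and 22791 USF2 peaks with no partner, a candidate explanation is that they lie near the calling threshold, where a site passes in one library and misses in the other. Sharing of 99.0% of the highest-scored 10% of USF1 peaks and 99.5% of those of USF2 goes with it. Above their list's median scored 30.9% of the unshared USF1 peaks and 28.0% of the unshared USF2 peaks. Most unshared peaks thus lay at or below the median, the direction that this explanation predicts. How many a threshold alone would leave above the median is not known, so these values do not decide. In the 5 lowest score classes the shared part stayed between 27.1% and 33.0% for USF1 and 33.7% and 40.7% for USF2. The threshold explanation therefore stays open. Peaks that lie side by side without touching are argued against as the whole cause. Of the unshared peaks, 15.0% for USF1 and 19.8% for USF2 were within 500 bp of a peak of the other list. The share that position alone would give was not measured. Sites bound by USF1 or USF2 alone also stay open and were not tested, and if the same antibody was used for both, as one of the labels has it, the unshared peaks would be differences between 2 libraries of that antibody.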
